A study of Homo sapiens with 12 samples.

How the data were processed

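ChIP-seq libraries had been made from H1 human embryonic stem cells with antibodies to YTHDF1, RNF2 and H2AK119ub, with input libraries beside them, in 2 biological replicates per group, per the labels. The 12 libraries comprised 8 immunoprecipitated and 4 input libraries in 6 groups, and each was assigned to its group from its title. The 4 deposited peak lists were analysed, each made by the authors from merged replicates. Peaks could therefore not be compared between replicates, and separate input or replicate signals were not analysed here.

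Per the submitters' processing notes, Trimmomatic 0.35, Bowtie2 2.2.5, SAMtools 1.3.1, Picard, MACS2 2.1.0 and SICER 1.1 had been used with the hg38 build, without roles or settings. The caller of each list was not given in the sources used here. The YTHDF1, RNF2 and knockdown YTHDF1 lists had the layout that MACS2 writes for narrow peaks. In them each peak carried the authors' fold enrichment, a −log10 of the p-value and a −log10 of the q-value, all as deposited. The deposited score was 10 times the −log10 p, cut to a whole number and capped at 1000. The H2AK119ub list carried a deposited score of unstated scale, capped at 1000 in 3494 of its islands, and its intervals were multiples of 200 bp, as SICER writes islands. Its ends name the last base of an island and were read so. The lowest −log10 q differed between deposited lists (1.502, 4.01 and 4.01 for wild-type YTHDF1, RNF2 and knockdown YTHDF1), so the number of peaks per list depends on the authors' thresholds as well as on the signal. The fold enrichments, −log10 values and scores were used to describe, rank or filter peaks within their list. The exception was a common −log10 q minimum applied to the wild-type and knockdown YTHDF1 lists, whose depth was unknown.

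Depth per library was unknown, and no statement on sensitivity of peak calling per library could be made from the lists. Coordinates are 1-based on hg38. Peaks on the 22 autosomes, X and Y were used. Gene positions and names came from a RefSeq gene table of GRCh38.p14, the same assembly, with 59679 genes on these chromosomes, 20037 of them protein-coding. No genome sequence was used here, and the table gives neither strand nor exons. Promoters in the design were therefore replaced by windows of 2 kb around both ends of each coding gene, and exons and introns by the part of coding genes outside these windows. Such windows also take in the 3′ ends of genes. GC content could not be used for strata and assembly gaps could not be left out of random placement.

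Peaks shared between lists were those that overlapped by at least 1 bp. For each pair, peaks of the first list were placed at random within their chromosome 1000 times with their widths kept (seed 7), the excess was the observed number over the mean of the placements, and the two-sided permutation p could not fall below 0.001. RNF2 peaks with and without YTHDF1, pairs of marks at gene ends and gene groups were compared by two-sided Fisher exact tests, with odds ratios and Woolf 95% intervals, for which 0.5 was added to each cell where one was 0. Strata were combined by the Mantel-Haenszel method. The 48 tests of 12 gene groups by 4 lists were adjusted by Benjamini-Hochberg and called at 0.05. Peaks and neighbouring genes are not independent replicates, so these p-values describe the lists. Shares carry exact (Clopper-Pearson) 95% binomial intervals. Wild-type and knockdown lists were compared by numbers, lengths and shares without a test, and the overlap of their positions was tested by placement.

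The gene groups and the rule for named genes were fixed before the data were examined. The rule took the genes of YTHDF1 and RNF2, the 4 members of each group with the strongest YTHDF1 peak at an end, the 10 genes with the strongest YTHDF1 peak among those with all 3 marks, and the 5 strongest knockdown peaks with and the 5 without a wild-type peak. A few of the genes this rule took are not reported here. Strength was the −log10 p, the uncapped form of the score. BMP4, the immediate early genes, RNA45SN1 and RNA45SN2 fall outside the rule and were named after their values had been seen. Of the genes listed, all were matched by symbol or synonym except 1 of 35 differentiated-tissue genes, whose symbol was ambiguous.

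Alternatives fixed before the data were examined were an overlap of at least 50% of the shorter peak or at the midpoint, the better-scoring 50% of each list, circular shifts, merging of peaks within 1 kb, autosomes alone, placement within 10 kb gene-end classes, windows of 500 bp and 5 kb, and covered base pairs in place of midpoints. Added after the data had been seen were 2 kb gene-end classes, placement outside 29 stretches of over 1 Mb without peaks or genes (189 Mb), a minimum −log10 q of 4, one of 8 for the numbers and shared positions of wild-type and knockdown YTHDF1 peaks, others up to 20 for their numbers alone, whole genes with 2 kb either side, deciles of gene length and placement of RNF2 peaks in 4 groups of fold enrichment.

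Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The placement test was tested on simulated data for YTHDF1 against RNF2 and against H2AK119ub, with 2000 simulated peaks, 100 simulations and 100 placements each. A planted excess of 10% of peaks was estimated at 9.91% for RNF2 and 9.81% for H2AK119ub and gave a p under 0.05 in 100 of 100 simulations of either pair. With no planted excess this happened in 3 of 100 for either pair. Simulated peaks that were not planted were placed by the same random rule as in the test. Clustering of peaks, assembly gaps and a preference for gene ends were therefore not simulated, and the check does not cover them. Overlap numbers of 6 pairs of lists were checked with bedtools 2.31.1 and were equal.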

Results

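Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map YTHDF1, RNF2 and H2AK119ub in H1 cells, an established human embryonic stem cell line. YTHDF1 is a reader of N6-methyladenosine (m6A) on RNA. RNF2 is a catalytic subunit of Polycomb repressive complex 1 (PRC1), and H2AK119ub is the ubiquitin mark on histone H2A that PRC1 writes. The 12 libraries fell into 6 groups of 2 replicates. In wild-type cells these were YTHDF1, RNF2, H2AK119ub and input, and in YTHDF1-knockdown cells they were YTHDF1 and input. The replicates of a group had been merged into 1 peak list by the authors, so there was no spread between replicates, and no p-value between wild-type and knockdown cells is given. Exact binomial 95% intervals are given for shares and cover counting error only. Sequencing depth was unknown, since the lists carry no read totals.

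The 4 lists differed widely in size and in the strength of their peaks. The wild-type YTHDF1 list held 44498 peaks covering 21.6 Mb, with a median width of 408 bp and a median fold enrichment of 2.89. The RNF2 list held 29310 peaks covering 66.5 Mb, with a median width of 1347 bp and a median fold enrichment of 3.74. The H2AK119ub list held 43331 islands covering 310.2 Mb, which was 10.05% of the placed chromosome extent, with a median width of 4600 bp. The knockdown YTHDF1 list held 226 peaks covering 115 kb, with a median width of 445.5 bp and a median fold enrichment of 4.01. The lowest −log10 q was 1.502 in the wild-type YTHDF1 list, 4.01 in the RNF2 list and 4.01 in the knockdown list. Of the wild-type YTHDF1 peaks, 69.0% lay below 3-fold enrichment and 97.6% had a −log10 q below 4. Fold enrichments, q-values and scores are the authors' own values for each peak. They were used within a list, except that common −log10 q minima were applied to both YTHDF1 lists, although their depth was unknown.

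The first question of the design was whether YTHDF1 sites coincided with sites of RNF2 and H2AK119ub in wild-type cells. The gene ends with the strongest YTHDF1 peaks that also carried both PRC1 features included several transcriptional regulators. EGR1, an immediate early zinc-finger transcription factor, had a 7.49-fold YTHDF1 peak at chromosome 5, 138464449 to 138465603 (hg38), over the lower-coordinate end of the gene (138465479 to 138469303). It overlapped a 6.74-fold RNF2 peak and an H2AK119ub island of 13.0 kb. The related gene EGR4 (chromosome 2, 73290929 to 73293548) had a 5.60-fold YTHDF1 peak inside a 6.05 kb RNF2 peak of 12.9-fold. SRF, a transcription factor of immediate early genes, and KMT2A, a histone H3K4 methyltransferase, had YTHDF1 peaks of 5.47-fold and 4.87-fold. ACAP2, RAB36 and ZNF787 had peaks of 8.23-fold, 6.02-fold and 5.47-fold, and the neighbours AJM1 and PHPT1 shared a 5.33-fold peak. The strongest peak of the list, at 74.7-fold, lay inside BMP4, a secreted bone morphogenetic protein, at chromosome 14, 53952070 to 53953593. It was within RNF2 and H2AK119ub domains of 25.1 and 28 kb, and fell in the end window of the predicted gene LOC124903317 but not in those of BMP4 (53949736 to 53956891).

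Across the whole list, 5641 of 44498 wild-type YTHDF1 peaks (12.7%, interval 12.4 to 13.0%) overlapped an RNF2 peak. Random placement of the same peaks within their chromosomes gave 1285 ± 35.5 (SD over 1000 placements), so the observed number was 4.39-fold higher. With H2AK119ub the overlap was 12609 peaks (28.3%, 27.9 to 28.8%) against 5474 ± 67.1 by placement, a 2.30-fold excess. Both permutation p-values were 0.001 (two-sided), the smallest that 1000 placements can give. Counted the other way, 5091 RNF2 peaks (17.4%) and 9339 H2AK119ub islands (21.6%) overlapped a YTHDF1 peak. Both PRC1 features lay on 5419 YTHDF1 peaks (12.2%), RNF2 alone on 222 (0.499%), H2AK119ub alone on 7190 (16.2%) and neither on 31667 (71.2%). The excess with RNF2 was 2.76-fold when each peak was placed within its own class of sequence, within 2 kb of a coding-gene end or farther. For YTHDF1 peaks with a −log10 q of at least 4 the excess was 12.6-fold with RNF2 and 3.75-fold with H2AK119ub. These 2 values come from placement within the chromosome, without gene-end classes, and do not compare with the 2.76-fold.

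**Figure D1:**
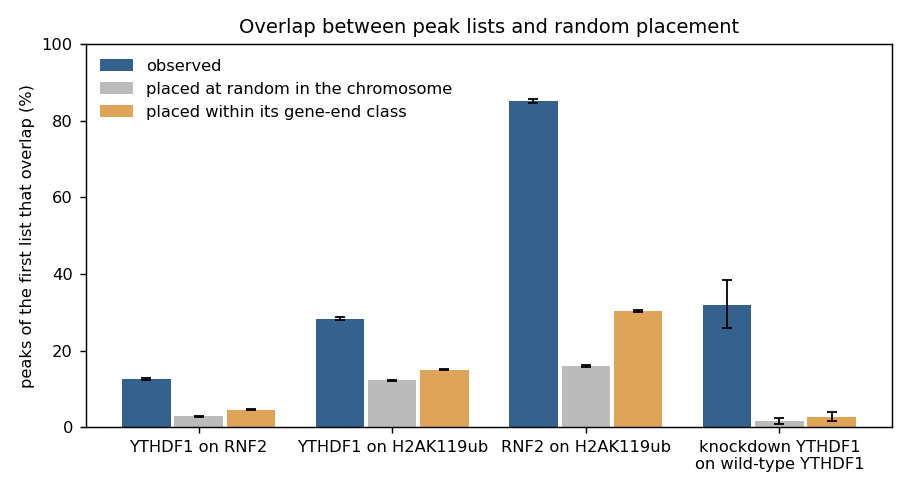
Share of peaks of the first-named list that overlapped the second (vertical axis, percent), observed (blue, 95% exact binomial interval), after random placement in the chromosome (grey) and after placement within the same gene-end class (orange), the last 2 with the SD over 1000 placements. Observed shares were 12.7%, 28.3%, 85.1% and 31.9%, and each lay above both placements.

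Strong YTHDF1 peaks lay on PRC1 features more often than weak ones. SOX1, a neural transcription factor whose strongest YTHDF1 peak had a −log10 q of 6.44, carried it inside a 34.3 kb RNF2 domain, and HOXB1 and SFTPC had such peaks at 5.21. Among 27793 peaks with a −log10 q from 1.5 to 2, 9.68% (9.33 to 10.03%) overlapped RNF2 and 25.4% (24.9 to 25.9%) H2AK119ub. Among the 1062 peaks with a −log10 q of at least 4, the shares were 42.9% (39.9 to 46.0%) and 55.9% (52.9 to 58.9%). The excess over placement rose from 3.41-fold to 12.5-fold for RNF2 and from 2.103-fold to 3.75-fold for H2AK119ub between these classes. The stronger peaks were also wider, with a median of 554.5 bp against 390 bp, and random placement kept these widths. Midpoints of peaks with a −log10 q of at least 4 lay within 2 kb of a coding-gene end in 34.3% of cases, against 12.2% for the whole list. Placement within gene-end classes was not run by strength, so the part of the rise that goes with position at gene ends is unknown.

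**Figure D2:**
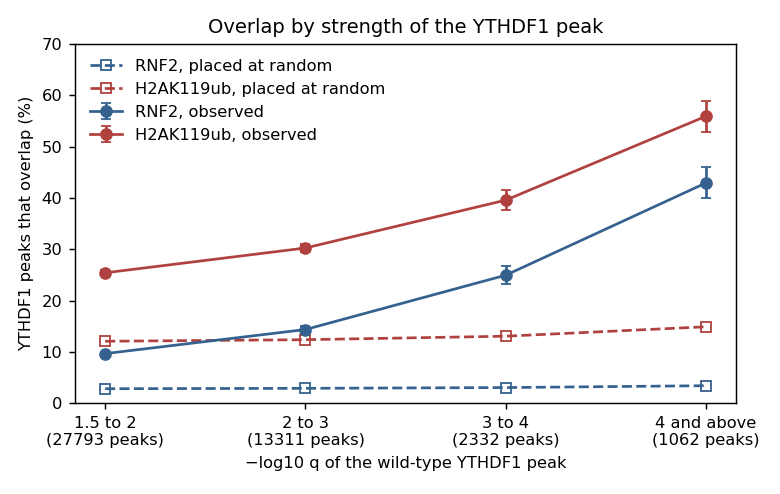
Share of wild-type YTHDF1 peaks that overlapped RNF2 (blue) or H2AK119ub (red) in 4 classes of −log10 q (horizontal axis), observed (filled circles, 95% exact binomial intervals) and after random placement (open squares). Observed shares rose from 9.68% to 42.9% for RNF2 and from 25.4% to 55.9% for H2AK119ub, while placement stayed between 2.84% and 14.9%.

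RNF2 and H2AK119ub, the writer and its mark, were compared as the reference pair. At the HOXA cluster of body-axis patterning genes on chromosome 7, a single RNF2 peak of 181 kb and a single H2AK119ub island of 180.2 kb covered the whole cluster. The HOXC and HOXD clusters were likewise covered over 100% of their length by 1 peak of each. The HOXB cluster (chromosome 17, 48528526 to 48728750) held 14 RNF2 peaks over 92.7% of its length and 3 H2AK119ub islands over 91.4%. Genome-wide, 24948 of 29310 RNF2 peaks (85.1%, 84.7 to 85.5%) overlapped an H2AK119ub island, 5.32-fold more than by placement (4689 ± 61.3, permutation p = 0.001, the smallest possible). In the reverse direction, 17268 islands (39.9%) overlapped an RNF2 peak. Placement within gene-end classes gave a 2.79-fold excess.

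The title of the series links YTHDF1 to H2AK119ub, and RNF2 peaks with and without a YTHDF1 peak were compared for the mark. RNF2 peaks at EGR1, SOX1 and FOXA2 belonged to the group with YTHDF1, and each lay on H2AK119ub. Of 5091 RNF2 peaks with a YTHDF1 peak, 4910 (96.4%) overlapped an H2AK119ub island, against 20038 of 24219 (82.7%) without one. The odds ratio was 5.66 (95% interval 4.86 to 6.59, two-sided Fisher exact p = 2.19e-178), where peaks are the units and not replicates. RNF2 peaks with YTHDF1 were wider (median 2075 against 1224 bp) and had a higher RNF2 fold enrichment (median 4.89 against 3.59). When RNF2 peaks were divided into 4 equal groups by their own fold enrichment, the share with a YTHDF1 peak was 7.16% in the lowest, 11.2% and 20.6% in the middle groups, and 30.5% in the highest. Their median width rose from 715 to 3083 bp, and random placement of these peaks gave 2.19%, 2.64%, 3.69% and 7.88%. The excess over placement was thus 3.28-fold, 4.26-fold, 5.58-fold and 3.87-fold, without a steady rise. Stratified by deciles of RNF2 peak width, the odds ratio was 2.88 (2.45 to 3.37). It was 2.57 among RNF2 peaks within 2 kb of a coding-gene end, 5.63 (4.59 to 6.91) among those farther away and 2.24 in the better-scoring 50% of each list.

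At the ends of protein-coding genes the pairs were compared again, with other genes as the background. The gene of YTHDF1 itself (chromosome 20, 63195429 to 63216131) carried a 2.72-fold YTHDF1 peak, a 6.29-fold RNF2 peak and H2AK119ub at its higher-coordinate end. Its YTHDF1 peak had a −log10 q of 1.58, near the list minimum of 1.502. The RNF2 gene (chromosome 1, 185045558 to 185102603) carried RNF2, at 7.66-fold, and H2AK119ub but no YTHDF1 peak. Of 20037 genes, 5838 (29.1%) had a YTHDF1 peak within 2 kb of an end, 13445 (67.1%) an RNF2 peak, 15219 (76.0%) an H2AK119ub island and 4839 (24.2%) all of them. Both ends of a gene were counted together, so marks at opposite ends also counted as shared. At EZH2 on chromosome 7, YTHDF1 lay at 148807975 to 148808270 and RNF2 at 148882422 to 148885559. RNF2 was present at 84.7% of genes with YTHDF1 and 59.9% of the others (odds ratio 3.70, 3.42 to 4.004, two-sided Fisher exact p = 3.55e-275). H2AK119ub was present at 92.3% and 69.2% (odds ratio 5.36, 4.84 to 5.94, p = 7.74e-310, Fisher exact test). RNF2 and H2AK119ub had an odds ratio of 41.3 (37.5 to 45.6). With YTHDF1 peaks of −log10 q of at least 4 the odds ratios were 10.1 with RNF2 and 17.1 with H2AK119ub, and in the better-scoring 50% of each list the second was 3.36 and that of RNF2 with H2AK119ub 19.7.

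Gene groups fixed before the data were examined were then tested for peaks at their ends, each against all other coding genes (two-sided Fisher exact test, Benjamini-Hochberg over 48 tests), and adjusted exact p-values are given. Developmental regulators carried PRC1 features at nearly every member. All 39 HOX genes had RNF2 and H2AK119ub (adjusted exact p = 3.69e-06 and 0.00029), as had all 28 neural developmental transcription factors (adjusted exact p = 0.000193 and 0.00301). The HOXA, HOXC and HOXD clusters each lay under 1 peak of either mark, so their genes are not independent units in this test. Of 24 mesoderm transcription factors, 22 had RNF2 (adjusted exact p = 0.0283) and 23 H2AK119ub, which did not pass (adjusted exact p = 0.0503) but passed in 4 of 5 alternatives. All 20 endoderm transcription factors had H2AK119ub (adjusted exact p = 0.0255) and 18 had RNF2, which did not pass (adjusted exact p = 0.0823) but passed in all 5 alternatives run, with odds ratios from 4.67 to 16.2. Of 31 secreted developmental signalling factors, 30 had RNF2 and 30 H2AK119ub (adjusted exact p = 0.000982 and 0.0194). The RNF2 peaks at these genes varied in size: 105-fold over 34.3 kb at SOX1, 78.9-fold over 42.8 kb at DLX2, 65.9-fold over 40.8 kb at HAND1, 79.9-fold over 38.5 kb at FOXA2 and 67.3-fold over 46.0 kb at WNT1, but 16.9-fold over 8.05 kb at CHRD, 14.7-fold over 9.35 kb at FGF8, 8.95-fold over 4.46 kb at WNT7A and none at MEOX1.

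YTHDF1 peaks were less evenly spread over the same groups. HOX genes carried a YTHDF1 peak more often than other genes, at 19 of 39 (48.7% against 29.1%, odds ratio 2.31, 1.23 to 4.34, adjusted exact p = 0.039). The strongest were 4.07-fold at HOXB1 (chromosome 17, 48526945 to 48527889), 3.19-fold at HOXA3 and 3.11-fold in a peak shared by HOXA10 and HOXA11. The neural factors had YTHDF1 at 11 of 28 (39.3%, adjusted exact p = 0.527), among them SOX1 at 4.35-fold, NEUROG2 at 3.23-fold, DLX2 at 3.07-fold and IRX3 at 2.94-fold. The mesoderm factors had it at 5 of 24, with WT1, MEOX1, HAND1 and PAX7 between 2.95-fold and 3.09-fold. The endoderm factors had it at 6 of 20, with 3.42-fold at FOXA2, 3.37-fold at FOXA1, 3.09-fold at GATA6 and 3.08-fold at SOX7. The signalling factors had it at 9 of 31, among them CHRD and FGF8 at 3.51-fold and 3.37-fold, WNT7A at 2.82-fold and WNT1 at 2.95-fold, and the YTHDF1 test passed for none of these 4 groups. Most of these peaks were weak. At a −log10 q of at least 4, YTHDF1 was left at 1 of the 28 neural factors. It was left at 0 of the mesoderm, endoderm and signalling factors, beside 2.41% of other coding genes. These counts cover gene ends only. The signalling factor BMP4 was not counted, since the 74.7-fold YTHDF1 peak inside it lay outside its end windows. The HOX excess did not pass with the better-scoring 50% of peaks (odds ratio 1.42) or with a −log10 q of at least 4 (1.07). It turned below 1 with windows of 500 bp (0.353) and over whole genes with 2 kb either side (0.892), and neighbouring HOX genes share peaks.

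Genes of the pluripotent state and of the machinery itself were tested in the same way. Of 28 pluripotency-associated genes, 10 had YTHDF1, 17 RNF2 and 25 H2AK119ub, and no mark passed, though H2AK119ub did in 2 of 5 alternatives. Their strongest YTHDF1 peaks were at ETV4 (3.52-fold), JADE1 (2.83-fold), FGF2 (2.89-fold) and SALL4 (3.09-fold). PRC1 subunit genes had H2AK119ub at 30 of 30 (adjusted exact p = 0.00206), RNF2 at 26 (adjusted exact p = 0.0564, but past the threshold in 4 of 5 alternatives) and YTHDF1 at 11. Among them CBX8, which encodes a chromodomain subunit, lay in an RNF2 domain of 66.3 kb on chromosome 17 with a YTHDF1 peak of 3.65-fold. USP7 and PHC1 had YTHDF1 peaks of 3.65-fold and 3.34-fold. PRC2 subunit genes had YTHDF1 at 7 of 13 (53.8%, adjusted exact p = 0.156), including JARID2 at 3.41-fold, EPOP at 3.52-fold, EZH2 at 2.94-fold and SUZ12 at 3.23-fold. RNF2 was at 10 and H2AK119ub at 12 of these 13 genes, and neither passed. The m6A writer, eraser and reader genes had YTHDF1 at 8 of 21, RNF2 at 18 and H2AK119ub at 16, and no mark passed. The demethylase genes FTO and ALKBH5 had 3.79-fold and 3.53-fold YTHDF1 peaks, and CBLL1 and VIRMA, of the writer complex, 2.96-fold and 2.82-fold. At a −log10 q of at least 4, YTHDF1 was left at 1 of 30 PRC1 subunit genes and 1 of 21 m6A genes. It was left at 0 of 28 pluripotency-associated and 0 of 13 PRC2 subunit genes.

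Among the comparison groups, genes of differentiated tissues and olfactory receptor genes fell lower, and the ribosomal protein genes depended on the setting. Ribosomal protein genes had YTHDF1 at 14 of 55, RNF2 at 43 and H2AK119ub at 48, with no test passed, and RPS23, RPLP2, RPL13 and RPL4 had YTHDF1 peaks from 3.03-fold to 3.23-fold. For RNF2 at these genes the better-scoring 50% of peaks gave an odds ratio of 0.443 in place of 1.76. Stratified by deciles of gene length it was 2.30, and that of H2AK119ub 2.64, and both passed. Over whole genes with 2 kb either side, ribosomal protein genes had YTHDF1 less often than other genes (odds ratio 0.378), and that passed. Genes of differentiated tissues had RNF2 less often, at 12 of 34 (35.3% against 67.2%, adjusted exact p = 0.000992), and H2AK119ub less often, at 17 of 34 (50% against 76.0%, adjusted exact p = 0.00433). YTHDF1 was at 6 of them (adjusted exact p = 0.356), among them the lung surfactant gene SFTPC at 4.07-fold, CKM at 3.09-fold and CD8A at 2.94-fold. Over whole genes with 2 kb either side, the lower share of YTHDF1 in this group passed as well (odds ratio 0.405). The 390 olfactory receptor genes had all marks less often, with YTHDF1 at 29 (7.44%, odds ratio 0.191, adjusted exact p = 2.6e-25), RNF2 at 9 (2.31%, adjusted exact p = 2.41e-170) and H2AK119ub at 17 (4.36%, adjusted exact p = 2.27e-207). The olfactory receptor genes OR4F15, OR9I1, OR1A2 and OR52N1 had YTHDF1 peaks from 2.94-fold to 3.64-fold with neither RNF2 nor H2AK119ub. At a −log10 q of at least 4, YTHDF1 was left at 1 of 34 genes of differentiated tissues. It was left at 0 of 55 ribosomal protein and 0 of 390 olfactory receptor genes. Knockdown YTHDF1 peaks lay at the ends of 106 coding genes in all, too few to compare the groups, and the test passed for none of the 12.

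**Figure D3:**
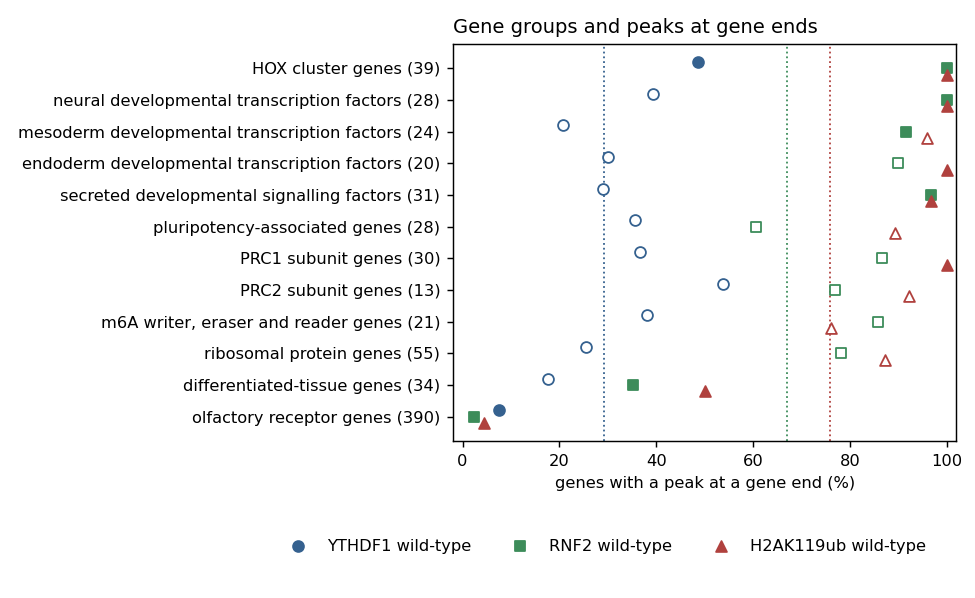
Share of the genes of each group with a peak within 2 kb of a gene end (horizontal axis, percent), for wild-type YTHDF1, RNF2 and H2AK119ub, with the number of genes in brackets. Filled symbols passed the Fisher exact test after adjustment, open symbols did not, and dotted lines mark all coding genes at 29.1%, 67.1% and 76.0%.

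Positions relative to genes differed between the lists and, for wild-type YTHDF1, with the strength of the peaks. Midpoints of RNF2 peaks lay within 2 kb of a coding-gene end in 42.4% of cases (41.9 to 43.0%), against 5.49% after random placement. For H2AK119ub islands the share was 24.1% (23.7 to 24.5%, placed 5.38%), and for wild-type YTHDF1 peaks 12.2% (11.9 to 12.5%, placed 4.89%). Of the knockdown YTHDF1 peaks 39.8% (33.4 to 46.5%, placed 6.35%) lay there, but this list began at a higher −log10 q. Of wild-type YTHDF1 peaks with a −log10 q of at least 4, 34.3% (31.4 to 37.2%, placed 5.71%) did so. Elsewhere inside coding genes lay 41.6% of wild-type YTHDF1 and 26.2% of RNF2 midpoints, and outside them 46.2% and 31.3%. With windows of 500 bp the shares at gene ends were 6.43% for wild-type YTHDF1, 27.9% for RNF2 and 9.91% for H2AK119ub.

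The second question of the design was how YTHDF1 signal differed between wild-type and knockdown cells. At BMP4, EGR4, SRF and RAB36 a wild-type YTHDF1 peak was called and no knockdown peak, whereas at EGR1, ACAP2 and KMT2A a peak was called in both. The wild-type list held 44498 peaks and the knockdown list 226, a ratio of 197, and the covered lengths were 21576 and 115 kb. Of the wild-type peaks, 72 (0.162%, 0.127 to 0.204%) overlapped a knockdown peak. The lists had different significance minima, and at a common −log10 q of at least 4 the numbers were 1062 and 226, a ratio of 4.70, with 38 wild-type peaks (3.58%, 2.54 to 4.88%) on a knockdown peak. The same −log10 q can stand for unlike p-values. With a lowest −log10 q of 4.01 in each, the lowest −log10 p was 9.03 in the knockdown list and 5.98 in the RNF2 list. At a minimum of 7 there were 96 and 98 peaks, and at a minimum of 8 the order turned, with 53 wild-type and 83 knockdown peaks (ratio 0.639). Knockdown peaks also outnumbered wild-type peaks at 10 (62 against 27), 15 (35 against 12) and 20 (21 against 9). Of the 20 strongest peaks of each list, 9 wild-type and 0 knockdown peaks lay below 10 Mb on chromosome 21, a region that holds ribosomal RNA genes. Some of the strongest knockdown peaks lay far from coding genes. No list of artefact-prone regions was applied, so these counts may include artefacts in either list.

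**Figure D4:**
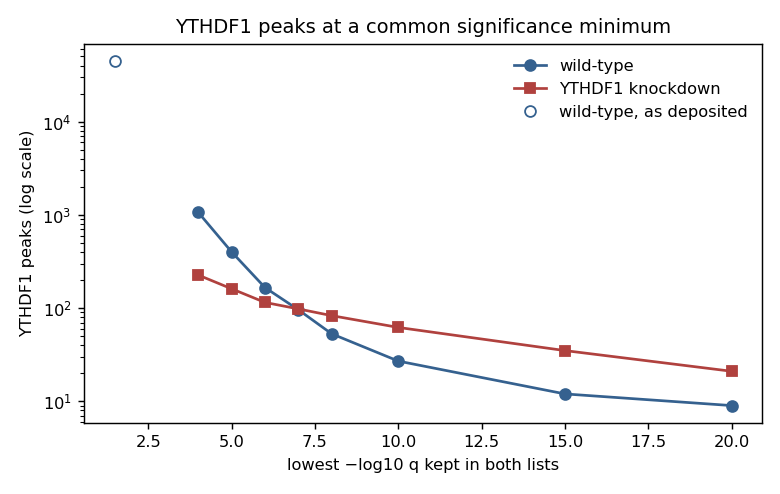
Number of YTHDF1 peaks (vertical axis, log scale) in wild-type (blue) and knockdown (red) lists that reached a given −log10 q (horizontal axis), with the wild-type list as deposited as an open circle. Wild-type peaks outnumbered knockdown peaks at a minimum of 4 (1062 against 226) and were fewer at 8 (53 against 83).

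Knockdown peaks lay where wild-type peaks had been called more often than by placement. The strongest knockdown peak that overlapped a wild-type peak was at EEF1A1, which encodes a translation elongation factor (chromosome 6, 73520010 to 73521319, 13.9-fold in the knockdown list). It was followed by EGR1 (138464799 to 138465591, 19.9-fold in the knockdown list), ZSWIM6 (7.90-fold), CFAP144 (7.96-fold) and a site 12.9 kb from CBX8 (8.02-fold). The wild-type peaks at these sites, from EEF1A1 to the CBX8 site, had lower values of 2.94-fold, 7.49-fold, 3.51-fold, 4.27-fold and 3.23-fold. The sites were picked by their knockdown strength and depth was unknown, so no change in signal follows from this. Of the 226 knockdown peaks, 72 (31.9%, 25.8 to 38.4%) overlapped a wild-type YTHDF1 peak, against 3.78 ± 1.91 by placement, a 19.1-fold excess (permutation p = 0.001, the smallest possible). The strongest without a wild-type peak were narrow peaks far from coding genes. The first was at chromosome 16, 34588105 to 34588356 (2.28-fold, −log10 q 97.5), 198 kb from LOC124903767. It was followed by chromosome 17, 26881271 to 26881542 (2.57-fold, −log10 q 68.4), 412.6 kb from WSB1. Then came chromosome 1, 143263424 to 143263719 (5.10-fold, −log10 q 40.8), 639 kb from H3-7. No list of artefact-prone regions was applied to these sites. The next were in TNFSF9 (6.85-fold) and over an end of CFAP54 (8.16-fold). RNF2 lay on 114 knockdown peaks (50.4%, 43.7 to 57.1%) and H2AK119ub on 127 (56.2%, 49.5 to 62.8%), 15.1-fold and 3.57-fold more than by placement. RNF2 lay on 60 of the 72 knockdown peaks with a wild-type peak and on 54 of the 154 without. The excess over wild-type YTHDF1 peaks was 11.3-fold with placement within gene-end classes. With placement within the chromosome, without these classes, it was 255-fold against wild-type peaks with a −log10 q of at least 4. There 38 overlapped and 0.149 were placed so by chance.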

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

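The overlaps and odds ratios between marks kept their direction and stayed past the threshold under every alternative run, some of which were chosen after seeing the data (2 kb gene-end classes, empty stretches left out, a minimum −log10 q of 4, whole genes, deciles of gene length). The excess over placement ranged from 2.76-fold to 12.6-fold for YTHDF1 on RNF2, 1.88-fold to 3.75-fold for YTHDF1 on H2AK119ub, 2.79-fold to 7.14-fold for RNF2 on H2AK119ub and 11.3-fold to 255-fold for knockdown on wild-type YTHDF1 peaks. The lowest of each came from placement within 2 kb gene-end classes, the highest from stronger peaks placed without such classes. The odds ratio for H2AK119ub at RNF2 peaks with YTHDF1 ranged from 2.24 to 6.52. At gene ends it ranged from 2.74 to 10.1 for YTHDF1 with RNF2, 3.36 to 17.1 for YTHDF1 with H2AK119ub and 19.7 to 46.5 for RNF2 with H2AK119ub.

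Peak numbers depended on the significance minimum. The ratio of wild-type to knockdown YTHDF1 peaks was 4.70 at a common −log10 q of 4 and reversed to 0.639 at 8, a minimum also chosen after seeing the data, where fewer peaks of each list remain by construction. The share of wild-type peaks on a knockdown peak was 3.58% and 20.8% at these minima and 9.29% among the 226 strongest wild-type peaks. Shares of midpoints at gene ends with 500 bp windows were 6.43% for wild-type YTHDF1, 27.9% for RNF2, 9.91% for H2AK119ub and 30.1% for knockdown YTHDF1, since the windows are narrower. By covered base pairs they were 15.5%, 41.3% and 20.7% for the wild-type lists in the same order. For wild-type YTHDF1 peaks with a −log10 q of at least 4, also chosen after seeing the data, the share was 34.3%, near the 39.8% of the knockdown list.

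Among gene groups, 1 carried YTHDF1 more often in the reported setting and 0 did with 500 bp windows, the better-scoring 50% of each list, whole genes or a −log10 q of at least 4. That group was HOX, whose odds ratio reversed to 0.353 with 500 bp windows and 0.892 over whole genes. Groups that carried YTHDF1 less often numbered 1 in the reported setting and 3 over whole genes. Those added over whole genes were ribosomal protein genes (odds ratio 0.378, adjusted exact p = 0.00265) and genes of differentiated tissues (0.405, adjusted exact p = 0.0372). The odds ratio of RNF2 at ribosomal protein genes reversed to 0.443 in the better-scoring 50% of each list (adjusted exact p = 0.0119), but rose to 2.30 by deciles of gene length, where H2AK119ub gave 2.64 and both passed. RNF2 at endoderm transcription factors missed the threshold as reported and passed in all 5 alternatives (4.67 to 16.2), H2AK119ub at mesoderm transcription factors and RNF2 at PRC1 subunit genes passed in 4 of 5, and H2AK119ub at pluripotency-associated genes in 2 of 5. The cause was not tested for any of these. For single groups, 222 other settings left the call where it was, 19 added a call in the same direction and 2 ended one in the same direction. Both of these were HOX, whose 2 reversed settings also ended the call, so 4 ended it in all. In 30 of the 222, the odds ratio crossed 1 with no call in either setting. The 222 include every setting of the knockdown YTHDF1 list, whose peaks were too few to compare the groups. Some of the 30 were knockdown tests in which 0 members had a peak. There the odds ratio lay above 1 only because 0.5 was added to each cell. Deciles of gene length gave no value in 6 cases in which every member carried the mark.

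No paired analysis was possible because the replicates of each group had been merged into 1 list. For the same reason the replicate block and leaving out each replicate were not run, and GC strata were not run for want of a genome sequence. Depth was unknown, so a site without a peak is one where none was called, not one without binding.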

Other observations

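The tests at a common significance minimum, of wild-type peaks called again in the knockdown, and of knockdown peaks on RNF2 were chosen only after those results had been seen. The tests of gene-end classes, of X peaks by RNF2 enrichment and of strong peaks at immediate early genes were written before their results, for patterns already noticed in the lists. The tests of immediate early genes with peaks of any strength and of X peaks by YTHDF1 strength were not written before their results.

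EGR1, EGR4 and SRF stood among the strongest YTHDF1 peaks with PRC1 features, and the strongest knockdown peaks included sites at EGR1 and JUND and a site 11852 bp from FOS (chromosome 14, 75294083 to 75294689). A hypothesis is that strong YTHDF1 peaks may favour immediate early genes, which respond to stimuli within minutes. Of 20 other immediate early genes, JUNB and IER2 had a YTHDF1 peak with a −log10 q of at least 4 at an end (10% against 2.40% of other coding genes, odds ratio 4.52, 1.05 to 19.5, two-sided Fisher exact p = 0.0825). That did not pass, and 20 genes are too few to decide. A YTHDF1 peak of any strength was present at 13 of the 20 (65.0% against 29.1%, odds ratio 4.52, p = 0.000938, Fisher exact test), among them JUN, ATF3, DUSP1, KLF6 and NR4A1. RNF2 was present at 18 of the same genes (90% against 67.1% of other coding genes) and H2AK119ub at 20 (100% against 75.9%). The YTHDF1 share was not compared with that of other genes that carry these marks, so it cannot be read as particular to immediate early genes. Zinc-finger genes with a ZNF symbol had YTHDF1 at 134 of 517 (25.9% against 29.2%, p = 0.106) and knockdown YTHDF1 at 3 (odds ratio 1.1, p = 0.755), by Fisher exact tests.

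Some of the strongest wild-type YTHDF1 peaks lay in a stretch of ribosomal RNA genes on chromosome 21. Below 10 Mb on this chromosome there were 14 wild-type YTHDF1 peaks, 9 of them among the 20 strongest of the list, and 12 lay between RNA45SN2 and RNA45SN1 (8205988 to 8446572), 7 of them over such a gene. Below 10 Mb there were also 8 H2AK119ub islands, 5 of them in this stretch, and 2 knockdown YTHDF1 peaks, none of them over a ribosomal RNA gene, but no RNF2 peak. No list of artefact-prone regions was used here. In the wild-type YTHDF1 list, 6828 of 44498 peaks shared the same −log10 p of 4.76.

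The knockdown list held 197 times fewer YTHDF1 peaks than the wild-type list. A difference in the significance thresholds of the deposited lists may account for much of this ratio, which fell to 4.70 at a common −log10 q of 4. The same −log10 q can stand for unlike p-values, so a common minimum need not set an equal threshold. What remained of the ratio depended on where the minimum was set, with a ratio of 0.639 at 8. Loss of YTHDF1 from chromatin in the knockdown stays open, with 9.29% of the 226 strongest wild-type peaks on a knockdown peak. Depth and enrichment of the libraries were unknown, so a difference between them was not tested and stays open as well.

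YTHDF1 peaks overlapped RNF2 and H2AK119ub beyond random placement. Excesses of 2.76-fold and 1.88-fold were left when peaks were placed within the same 2 kb gene-end class. This argues against a shared, even spread over these windows as the whole cause. Within 500 bp of an end lay 6.43% of YTHDF1 midpoints (placed at random 1.37%) and 27.9% of RNF2 midpoints (placed 1.51%). The test spread peaks evenly over windows at both ends of genes, so it cannot decide on a shared position closer to particular ends. Signal that does not depend on YTHDF1, such as open or readily sheared chromatin, may still contribute, since 50.4% of knockdown peaks overlapped RNF2 beside 42.9% (39.9 to 46.0%) of wild-type peaks over the same minimum. Protein left after knockdown predicts the same share, so these cannot be told apart. A contact between YTHDF1 and PRC1 was not tested and stays open.

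Few wild-type YTHDF1 peaks lay on the X chromosome, 93 of 44498 (0.209%, 0.169 to 0.256%), a density 25.9-fold below that of the autosomes, beside 3.72-fold for RNF2 and 4.24-fold for H2AK119ub. H1 cells carry a single X chromosome, and its lower copy number may push weakly enriched peaks below the threshold. In that case X peaks should be rarest among weak RNF2 peaks, and their share was 1.21% (0.976 to 1.49%) in the lowest of 4 groups of RNF2 fold enrichment and 1.36% (1.11 to 1.66%) in the highest, with intervals that overlap. Strong YTHDF1 peaks were not seen to be less depleted on X, with 1 of 1062 at a −log10 q of at least 4 (0.0942%, 0.00238 to 0.524%), and of RNF2 peaks 2.61% (1.31 to 4.63%) on X and 17.6% (17.15 to 18.03%) on autosomes carried YTHDF1. A single strong peak is too few to decide, which leaves copy number open, and no biological explanation was tested.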
